A study of Homo sapiens with 20 samples.

How the data were processed

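RNA was measured in 20 sequencing libraries from 10 lines of fibroblast-like synoviocytes, the mesenchymal cells of the joint lining, grown from joint tissue of people with rheumatoid arthritis. Per the labels, 5 lines came from hips and 5 from knees. Each line gave a library labelled Med and a library labelled IL6. Per the labels' protocols, cells were grown in 10% fetal calf serum, used at passages 3 to 4, kept for 18 h in 0.1% serum and treated with interleukin 6 (IL-6) at 7.5 ng/ml for 2 h. The labels do not spell out Med, which is used here as the name of the libraries without the IL6 label.

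Per the submitters' processing notes, CASAVA, FastQC, cutadapt, HISAT2 and HTSeq were used with the genome build hg38. The notes give these names without versions, roles or order. The tool that made the log values, the annotation version and whether HTSeq counted by strand are not given in the sources used here. The authors deposited a table of log2 CPM (CPM are read counts scaled by library depth) for 16270 genes. Its values had a common floor of -2.232, or 0.2129 CPM, which fits a small prior count added before the log. The differences between low values corresponded to whole reads: below 1000 reads, 100% of the values in each library lay within 0.1 read of a whole number. The reads recovered in this way summed to between 8323709 and 10473586 per library.

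Depth sets what low genes can show, since a gene at the floor in every library of a group may still be transcribed. For a group with 0 reads, a lower bound on the fold was computed against a floor of 3 reads over the group. For a group with 1 to 3 reads, the ratio was computed with an exact 95% interval. Both cover counting error only. A fold change is on the log2 scale of the deposited values, prior included, and so understates the change of low genes.

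Gene symbols and coordinates came from GENCODE v29 on GRCh38, which matched 16231 of the genes by identifier. XIST, TSIX and Y-linked genes, 3 genes in all, were left out of every test. A filter of more than 1 CPM in at least 5 libraries removed 0 genes, since every deposited gene was above 1 CPM in at least 7 libraries, and 16267 genes were tested.

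Tests used limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on expression level. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05, and are two-sided. The response to IL-6 was fitted over all 20 libraries with a term for each line and separate IL-6 terms for hip and knee lines. From this fit came the mean response over all lines, the response in hip lines, the response in knee lines and their difference. Hip lines were compared with knee lines in separate fits of the 10 Med and the 10 IL6 libraries. Line was kept as a block in the IL-6 tests because the titles give the same line number once under each label within a joint. Replicate numbers 1 to 5 used here follow the order of the samples and only name a line.

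The pairing was checked in the values. The deviations of a line's Med and IL6 libraries from their group means correlated between 0.534 and 0.783 across genes. All 10 lines correlated best with their own partner. The labels do not say that the lines came from separate donors, so p-values measure the spread between these lines. No pair of libraries of a group agreed within counting noise, with a chi-square of at least 9.91 per degree of freedom, so no library was treated as deposited a second time.

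Before the data were examined, 24 gene lists were fixed, covering signalling, inflammation, matrix, developmental regulators, metabolism and markers of other cell types. Counts of members past the threshold are given over all genes tested and, again, adjusted over the list alone. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The mean response of 4 lists per line was compared between joints by an exact two-sided permutation test over the 252 assignments of 10 lines.

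Genes to be named were also set by rule before the data were examined. For the IL-6 response over all lines and for hip against knee in Med, these were the 10 higher and 10 lower genes with the largest log2 fold change past the threshold. For the other comparisons 5 were taken in each direction, or the 5 with the smallest p where none passed. IL-6 genes also had to move the same way in at least 9 of 10 lines, or in all 5 lines of a single joint. Eligible genes had a symbol that is not a clone name, were not among the genes left out or genes with a common whole-gene deletion, and had a mean of at least 1 log2 CPM in the higher group. Up to 4 members of each list with the smallest p, and SOCS3, STAT3, JAK1, JAK2, TYK2, IL6R and IL6ST, were named in any case. Where a list had 5 or fewer members in a direction, others were named too, and these were chosen after their values were seen. Some genes that this rule names are not reported here.

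The procedure was tested on simulated data for the 16267 genes with 200 genes changed. At a change of 1 on the log2 scale it recovered 95.5% of changed genes for the IL-6 response over all lines, 88.1% in hip lines, 89.6% in knee lines and 85.1% for their difference. It recovered 74.6% for hip against knee in Med and 79.1% in IL6. At 0.5, recovery was 86.6%, 74.6%, 73.1%, 55.2%, 28.4% and 26.9% in the same order. In these simulations false calls made up between 2.79% and 8.67% of calls. Genes were simulated independently of each other and without whole-library differences between joints. The real libraries may therefore have other shares of false calls.

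Alternatives set in advance were no replicate block, line as a random effect, quantile normalization, median centring, no filter, a mean of at least 3 log2 CPM, log2(CPM + 1), no variance trend, robust moderation, array weights and leaving out each line in turn. Added after seeing the data were limma-voom on the recovered reads, removal of each library's trend on GC content and length, and the list test with no replicate block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.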

Results

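Gene expression was measured by sequencing of total RNA from cultured fibroblast-like synoviocytes of people with rheumatoid arthritis. The libraries formed 4 groups of 5: hip lines in Med, hip lines in IL6, knee lines in Med and knee lines in IL6. Reads recovered over the deposited genes summed per library to 8448366 to 9929491 in hip Med and 8977219 to 10107618 in hip IL6. In knee lines the sums were 8323709 to 10473586 in Med and 8935806 to 10163547 in IL6. The design asks what IL-6, a cytokine that signals through JAK kinases and STAT transcription factors, did in these cells, whether hip and knee lines responded alike, and how the lines of the 2 joints differed.

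After 2 h of IL-6, synoviocytes from both joints raised APOL4, IRF1, SBNO2 and HAS1 and lowered RAB3A and DDIT4. APOL4, an apolipoprotein L gene, rose 18.5-fold, from a mean of 1.13 to 23.7 CPM in hip lines and from 1.36 to 25.7 CPM in knee lines. IRF1, a transcription factor of the interferon response, rose 8.03-fold, and SBNO2, a transcriptional regulator induced through STAT3, rose 6.14-fold. HAS1, which makes hyaluronan, rose 6.67-fold. Genes that fell included RAB3A, a GTPase of vesicle release, by 1.62 on the log2 scale, and DDIT4, an inhibitor of mTORC1, by 1.11. Each of these genes moved the same way in all 10 lines.

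In the limma fit with line as a block, 4296 of 16267 genes passed, 2172 higher and 2124 lower in IL6. Of these, 191 changed at least 2-fold, 172 higher and 19 lower. The log2 fold change was 4.21 for APOL4 (SE 0.17, adjusted p = 1.61e-15, n = 10 lines), 3.01 for IRF1 (SE 0.143, adjusted p = 3.01e-14) and 2.62 for SBNO2 (SE 0.0591, adjusted p = 2.54e-20). Other genes among the 10 with the largest rise were BATF3 (3.04), an AP-1 family factor, KIAA0040 (2.83), LZTS1 (2.80), KLF10 (2.66), a zinc finger factor, GBP1P1 (2.45) and TEAD4 (2.45), a factor of the Hippo pathway. BATF3 had at most 4 reads in any Med library and 12 to 45 in IL6. GBP1P1 is a pseudogene of GBP1, which rose by 2.37, so its reads may be shared and its value is uncertain. Besides RAB3A (-1.62) and DDIT4 (-1.11), the genes with the largest fall were the nuclear receptor NR0B1 (-1.33), NYAP1 (-1.33), the RNA-binding CPEB3 (-1.27), the limb factor TBX5 (-1.20), the cAMP phosphodiesterase PDE4B (-1.20), the potassium channel KCNJ2 (-1.15), the coactivator PPARGC1A (-1.14) and DDIT4-AS1 (-1.13). IRF1, RAB3A, TBX5, DDIT4 and DDIT4-AS1 overlap another annotated gene, and the strand of counting is not given, so their counts are uncertain to that extent.

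On GRCh38 (GENCODE v29), APOL4 (ENSG00000100336) lies on chromosome 22 from 36189124 to 36204840. IRF1 (ENSG00000125347) lies on chromosome 5 from 132481609 to 132490798, and SBNO2 (ENSG00000064932) on chromosome 19 from 1107636 to 1174283. SOCS3 (ENSG00000184557) lies on chromosome 17 from 78356778 to 78360077.

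With no replicate block the IL-6 response gave 1452 genes, 994 higher and 458 lower, and all 1452 were among the 4296, without KCNJ2. Under quantile normalization 4937 genes passed, 2031 higher and 2906 lower, so the share higher went from 50.6% to 41.1%. With the GC and length trend removed, a setting chosen after seeing the data, 2282 were higher and 2505 lower, so the balance of rises and falls depends on the normalization.

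**Figure D1:**
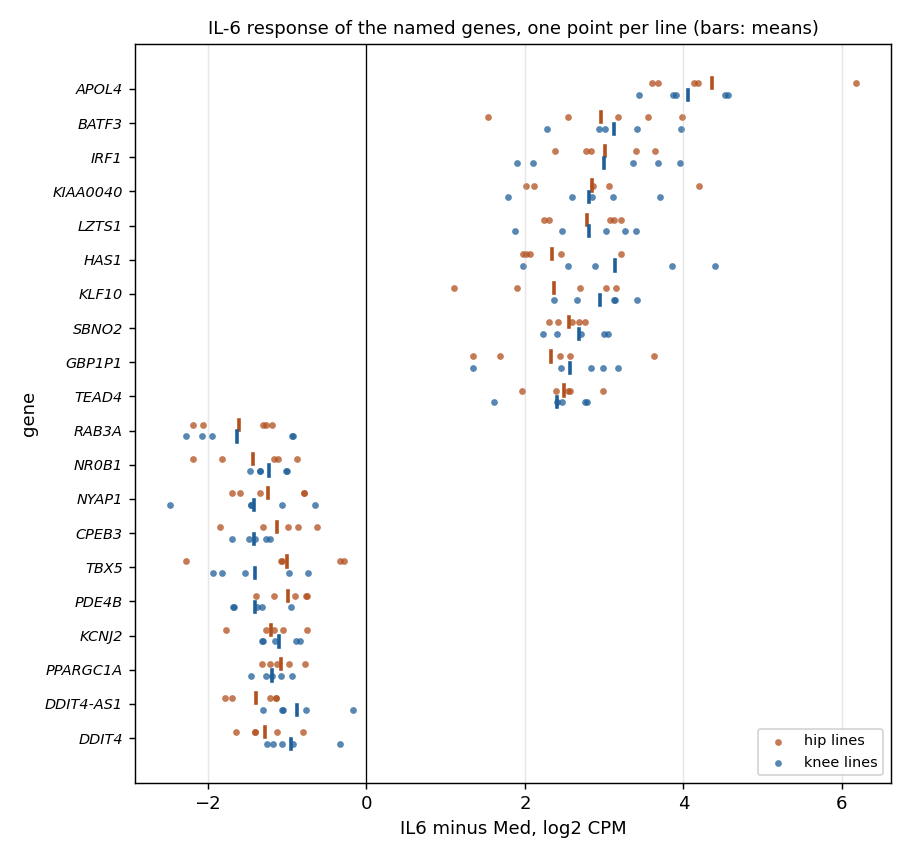
The 20 genes with the largest rise or fall, 10 in each direction, on the vertical axis, and the difference between IL6 and Med of each line in log2 CPM on the horizontal axis. Points are lines, 5 hip and 5 knee, and vertical bars are joint means; every line lies above 0 for the genes that rose and below 0 for those that fell, and the APOL4 mean is 4.06 in knee lines.

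Several components of the pathway itself also changed with IL-6. SOCS3, the feedback inhibitor of JAK signalling, rose by 1.23 (SE 0.0931, limma adjusted p = 1.49e-10), JAK2 by 1.14 (SE 0.0526) and STAT3 by 0.89 (SE 0.0428), each in 10 of 10 lines. IL6R, the ligand-binding receptor chain, fell by 0.65 (SE 0.0697, adjusted p = 6.19e-08) in 10 of 10 lines. IL6ST, the signal-transducing chain gp130, rose by 0.16 (SE 0.0331, adjusted p = 0.000527) in 9 of 10 lines, and it did not pass with no replicate block. JAK1 (0.01, SE 0.028, adjusted p = 0.898) and TYK2 (0.03, SE 0.0349, adjusted p = 0.626) did not pass. In the list of JAK-STAT components, which shares members such as OSMR and IL6ST with the STAT3 target list, 15 of 31 tested members rose and 2 fell, with 15 and 2 adjusted over the list alone (camera adjusted p = 4.12e-07). Its adjusted p was 0.0401 with an estimated correlation. The members that fell were IL6R and SOCS7.

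Known STAT3 targets rose as a group: 18 of 20 were higher and 0 lower, with 18 and 0 adjusted over the list alone. Among them were SBNO2, JUNB (2.07), BCL3 (1.80) and OSMR (1.12), the oncostatin M receptor chain. The list passed with camera (adjusted p = 4.4e-26) and had an adjusted p of 0.0401 with an estimated correlation. Interferon-stimulated genes rose in 17 of 27 cases and none fell, with 19 higher and 0 lower adjusted over the list alone. Examples were IRF1, GBP1 (2.37) and IFIT3 (1.41). With camera the adjusted p of the list was 8.75e-12, and the adjusted p was 0.131 with an estimated correlation.

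Inflammatory mediators rose in 10 of 19 cases and 1, the NF-kappaB inhibitor TNFAIP3, fell. Adjusted over the list alone, 11 rose and 1 fell. CCL2, a chemokine for monocytes, rose by 2.41, the adhesion molecules ICAM1 and VCAM1 by 1.81 and 0.83, and TNFAIP6 by 1.27. The camera adjusted p was 9.05e-07, and the adjusted p was 0.102 with an estimated correlation. Immediate early genes rose in 18 of 28 cases and 3 fell (DUSP4, KLF4 and KLF6), with 18 and 4 adjusted over the list alone. FOSL2 (1.72), JUNB (2.07), ATF3 (2.21) and KLF10 (2.66) were examples. For this list the camera adjusted p was 8.6e-11, and the adjusted p was 0.149 with an estimated correlation. VCAM1 did not pass with no replicate block.

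Among matrix proteases and their inhibitors 6 of 28 rose and 4 fell, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.0824). PLAU, the urokinase protease, rose by 2.23, its receptor PLAUR by 0.78 and the cathepsin CTSL by 0.52. Those that fell were ADAMTS5, ADAMTS1, CTSK and MMP19. Extracellular matrix genes rose in 7 of 37 cases and 5 fell (COL1A2, COL4A2, DCN, COL14A1 and COL6A3, by at most 0.11), with 8 and 6 adjusted over the list alone (camera adjusted p = 0.94). In the TGF-beta response list 11 of 26 rose and 4 fell, with 12 and 4 adjusted over the list alone. ID3 rose by 1.29, CCN2 by 1.58 and SKIL by 1.44, while INHBA, BAMBI, BMP2 and TGFB2 fell. The camera adjusted p of this list was 0.028, and the adjusted p was 0.339 with an estimated correlation.

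In the hypoxia and glycolysis list 8 of 21 rose and 3 fell (ADM, DDIT4 and ALDOC), with 8 and 4 adjusted over the list alone. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.32, the glucose transporter SLC2A3 by 1.17 (hip replicate 3 at 1.66, the next hip line at 1.12) and hexokinase HK2 by 1.14, while ADM fell by 0.68. The list's median was -0.031 and its mean 0.195, with a camera adjusted p of 0.0404. The adjusted p was 0.149 with an estimated correlation and 0.196 with no replicate block. Cholesterol synthesis genes rose in 5 of 23 cases and 3 fell (MVK, FDFT1 and HSD17B7), with 5 and 3 adjusted over the list alone (camera adjusted p = 0.478). INSIG1, a regulator of sterol sensing, rose by 0.37, IDI1 by 0.25 and HMGCS1 by 0.22. Cell cycle genes fell in 9 of 30 cases and 1, MCM6, rose, with 10 and 1 adjusted over the list alone. KIF11 fell by 0.34, TPX2 by 0.32 and MCM2 by 0.22. The camera adjusted p was 0.0404, and the adjusted p was 0.252 with an estimated correlation. INSIG1, IDI1, KIF11, TPX2, MCM2 and MCM6 did not pass with no replicate block, and MCM2 did not pass without hip replicate 2.

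Markers of other cell types ranged widely in level: the highest were CD14 at a mean of 3.2 log2 CPM for macrophages, CD4 at 1.95 for lymphocytes, ERG at 4.42 for endothelium, TAGLN at 7.62 for pericytes and smooth muscle, and ACAN at 8.09 for chondrocytes and osteoblasts. Medians over the tested members were lower, at 0.42 log2 CPM for macrophages, 1.52 for lymphocytes and 1.1 for endothelium. They were 2.75 for pericytes and smooth muscle and 1.36 for chondrocytes and osteoblasts. CD14 rose by 0.24 among 3 tested macrophage markers, with the same count adjusted over the list alone. None of 4 lymphocyte markers passed either way (CD79B -0.28, CD4 -0.26, JCHAIN 0.14, IL7R -0.06). Of 7 endothelial markers ERG rose by 0.19 and CDH5 fell by 0.36 (knee replicate 5 at -1.43, the next knee line at -0.41), also adjusted over the list alone. Among 10 pericyte and smooth muscle markers TAGLN rose by 0.27 and DES by 0.34 (hip replicate 1 at -0.04, the next hip line at 0.49), with 1 higher adjusted over the list alone. Of 5 adipocyte markers G0S2 rose and CEBPA and LIPE fell, with 1 and 3 adjusted over the list alone. SOX9 and RUNX2 rose and CHAD fell among 9 chondrocyte and osteoblast markers, also adjusted over the list alone. Lining fibroblast markers rose in 3 of 10 cases (HAS1, HBEGF and ITGB8) and HTRA1 fell, also adjusted over the list alone. Of 17 sublining markers CDH11, CD248, GGT5 and THY1 rose and DPP4 fell, with 4 and 2 adjusted over the list alone. Among 15 mitochondrially encoded genes MT-ND1 rose and MT-RNR2 fell, also adjusted over the list alone. Of 9 histone genes 3 fell, H2AC6 and H2BC5 among them, also adjusted over the list alone. Camera adjusted p-values of the cell type, mitochondrial and histone lists lay between 0.0824 for histones and 0.965 for pericyte and smooth muscle markers. CD14, ERG, CDH5, TAGLN, DES, CEBPA, G0S2, LIPE, MT-ND1, MT-RNR2, H2AC6 and H2BC5 did not pass with no replicate block. In the 10 fits without 1 line the call was lost in 8 for DES, 5 for CD14 and H2BC5 and 3 for CDH5. With line as a random effect DES, CD14, CDH5, ERG, G0S2, MT-ND1 and MT-RNR2 were lost, with no variance trend DES, CD14 and CDH5, with quantile normalization H2BC5 and MT-RNR2, and with robust moderation TAGLN.

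Hip and knee lines raised and lowered many of the same genes. In hip lines IL-6 changed 2329 genes, 1454 higher and 875 lower, and in knee lines 2656, 1512 higher and 1144 lower. Of these, 1148 were higher in both joints, where independent lists would share 135.1, and 521 were lower in both, against 61.54. No gene passed in opposite directions. Across all genes, which are not independent replicates, the responses of hip and knee lines had a Pearson r of 0.779 and a Spearman rho of 0.607. The 2 sets of lines share no library, but both responses came from the same fit, with a shared variance for each gene. Genes with little spread pass more easily in both joints, which can raise the shared counts above those of independent lists.

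The leading genes were APOL4 in hip lines (4.35, SE 0.24, limma adjusted p = 2.34e-12, n = 5) and in knee lines (4.06, SE 0.24, adjusted p = 5.98e-12, n = 5). In hip lines IRF1 (3.01), BATF3 (2.96), KIAA0040 (2.85) and LZTS1 (2.79) followed, and in knee lines HAS1 (3.13), BATF3 (3.12), IRF1 (3.00) and KLF10 (2.94). The genes with the largest fall in hip lines were RAB3A (-1.60), NR0B1 (-1.43), DDIT4-AS1 (-1.39), DDIT4 (-1.28) and the zinc finger gene ZNF396 (-1.25). In knee lines these were RAB3A (-1.63), NYAP1 (-1.42), CPEB3 (-1.41), TBX5 (-1.40) and PDE4B (-1.40). In hip lines the APOL4 response of replicate 3 was 6.18, and that of the next line 4.18. With no replicate block 529 genes passed in hip lines and 634 in knee lines, and NR0B1 and ZNF396 in hip lines and PDE4B, IL6R and IL6ST in knee lines did not pass. IL6ST in knee lines also lost its call with line as a random effect, quantile normalization or no variance trend. Under quantile normalization the hip split was 1318 higher and 1323 lower, and the knee split 1377 higher and 1497 lower.

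The question in the study's title is whether this signalling depends on the joint. SOCS3 rose by 1.05 in hip lines (SE 0.132, n = 5) and by 1.41 in knee lines (SE 0.132, n = 5), and the difference of -0.36 (SE 0.186, limma adjusted p = 0.999) did not pass. JAK2 rose by 1.16 and 1.12 (difference 0.04, SE 0.105) and STAT3 by 0.85 and 0.92 (difference -0.07, SE 0.0856). The differences for JAK1 (0.01, SE 0.056), TYK2 (0.00, SE 0.0698), IL6R (-0.09, SE 0.139) and IL6ST (-0.05, SE 0.0663) did not pass either, each with an adjusted p of 0.999.

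Over all genes, 0 of 16267 passed in the limma test of hip minus knee, and 0 passed in limma-voom on the recovered reads. At an unadjusted p under 0.05 there were 706 genes, where chance gives 813. The genes with the smallest p were B4GALT1 (-0.33, SE 0.0739), the growth factor gene HBEGF (-1.39, SE 0.332), OSR1 (0.44, SE 0.107), the nuclear long RNA MALAT1 (0.45, SE 0.11) and GOLGA8B (0.74, SE 0.183), all with an adjusted p of 0.829. In the self-test 85.1% of simulated differences of 1 on the log2 scale were recovered, and 55.2% of those of 0.5. That simulation changed 200 genes, which makes the adjusted threshold easier to reach. If only a few genes differ, recovery would be lower, so differences of this size in single genes may have been missed. Without knee replicate 2, 6 genes passed, with a hip minus knee difference above 0 for MALAT1, NEAT1, MEG3 and GOLGA8B and below 0 for JUNB and B4GALT1.

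The mean response of STAT3 targets per line was 0.983 ± 0.156 in hip lines and 1.15 ± 0.349 in knee lines (SD, n = 5 each). The difference of -0.164 had an exact two-sided permutation p of 0.333 (adjusted p = 0.444 over 4 lists), where the smallest possible p is 0.00794. For interferon-stimulated genes the values were 0.473 ± 0.119 and 0.70 ± 0.307 (SD, n = 5 each, exact permutation p = 0.19, adjusted p = 0.444). Inflammatory mediators had 0.551 ± 0.225 and 0.686 ± 0.214 (SD, n = 5 each, exact permutation p = 0.31, adjusted p = 0.444). Immediate early genes had 0.647 ± 0.31 and 0.739 ± 0.241 (SD, n = 5 each, exact permutation p = 0.611, adjusted p = 0.611). In each list all 10 lines had a mean response above 0.

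**Figure D2:**
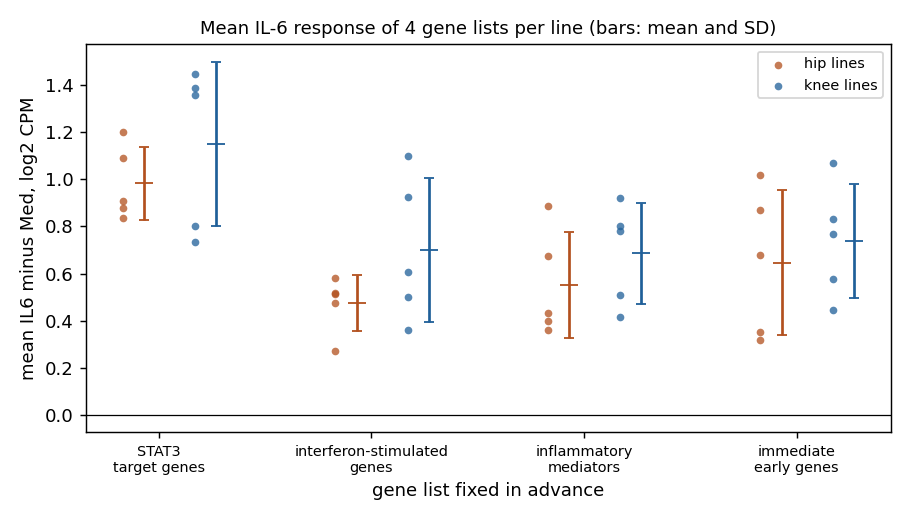
Mean difference between IL6 and Med over the members of 4 gene lists, in log2 CPM on the vertical axis, for each of 5 hip and 5 knee lines. Points are lines, horizontal marks are means and error bars are SDs; the STAT3 target means are 0.983 in hip and 1.15 in knee lines, and the points of the 2 joints overlap in each list.

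Hip and knee synoviocytes in Med differed in genes that pattern the body axis and the limbs. HOXB2, HOXB3 and HOXB4, neighbouring homeobox genes, were higher in hip lines, as was HAND2, a transcription factor of embryonic patterning. HOXD9, HOXD10, PITX1, a factor of hindlimb identity, and TBX5, a limb T-box factor, were higher in knee lines. HOXB3 was at a mean of 10.1 CPM in hip and 0.459 CPM in knee lines, HAND2 at 40 and 8.2 CPM, TBX5 at 1.31 and 11.1 CPM, and PITX1 at 35.6 and 99.9 CPM.

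In limma 85 genes passed, 51 higher and 34 lower in hip lines, and 34 differed at least 2-fold. HOXB3 differed by 3.89 (SE 0.42, adjusted p = 0.00582, n = 5 lines per joint) and HOXB4 by 3.76 (SE 0.299, adjusted p = 0.000702). Also among genes higher in hip lines were the protocadherin PCDH10 (3.26), HOXB-AS1 (3.01), HOXB2 (2.93), AJAP1 (2.57), EYA1 (2.50), HAND2 (2.36) and HAND2-AS1 (2.25). Genes higher in knee lines were HOXD10 (-3.30, SE 0.501, adjusted p = 0.0236), TBX5 (-3.07, SE 0.382, adjusted p = 0.0107), C14orf39 (-2.21), PSG1 (-2.14), HOXD9 (-1.93), the adipokine gene RARRES2 (-1.76), the transporter ABCB5 (-1.72), IL12A-AS1 (-1.61), IL12A (-1.57), which encodes a subunit of interleukin 12, and PITX1 (-1.56). HOXB2, HOXB3, HOXB4, HOXB-AS1, HAND2, HAND2-AS1, EYA1, IL12A, IL12A-AS1, HOXD9, PITX1 and TBX5 overlap another annotated gene, so reads may be shared, and PSG1 belongs to a family of near-identical paralogs. Their values are uncertain to that extent.

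Counts were low for some of these genes. HOXB7 had 92 reads over the 5 hip lines in Med and 0 over the 5 knee lines, so it was at least 33.5-fold higher in hip lines against a floor of 3 reads over the group. HOXB4 had 137 reads against 1, which came from knee replicate 1, a ratio of 150 with a 95% counting interval of 26.4 to 5960. HOXD10 had 3 reads in hip and 149 in knee lines, a ratio of 45.4 in favour of knee (15.3 to 223). In knee lines HOXB2 was at 1.75 log2 CPM in replicate 5 and at 0.00 in the next line, and IL12A-AS1 at 0.78 in replicate 3 and at 1.14 in the next. In hip lines TBX5 was at 1.84 in replicate 5 and at 0.20 in the next line.

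On GRCh38 (GENCODE v29), HOXB3 (ENSG00000120093) lies on chromosome 17 from 48548870 to 48604912 and spans HOXB4 (ENSG00000182742), from 48575513 to 48580111. HOXD10 (ENSG00000128710) lies on chromosome 2 from 176108790 to 176119942 and HOXD9 (ENSG00000128709) from 176122720 to 176124937. TBX5 (ENSG00000089225) lies on chromosome 12 from 114353931 to 114408442, and PITX1 (ENSG00000069011) on chromosome 5 from 135027735 to 135034813.

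**Figure D3:**
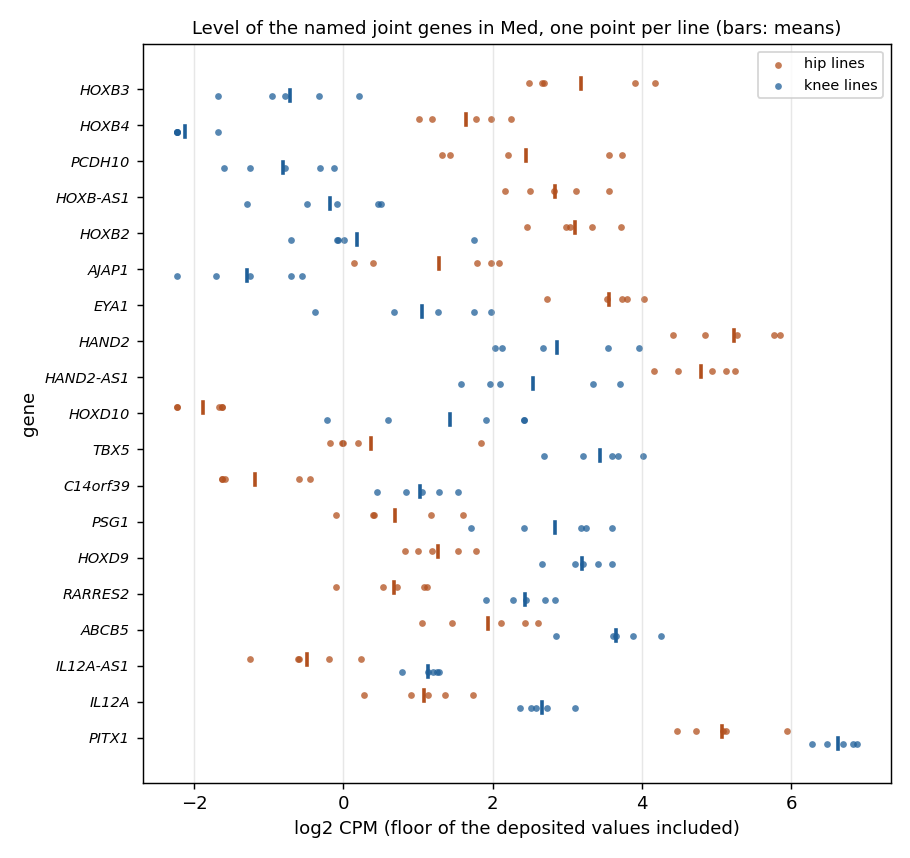
Of the genes with the largest difference between hip and knee lines in Med, 9 higher in hip and 10 higher in knee lines, on the vertical axis, and their level in log2 CPM on the horizontal axis, where -2.232 is the floor of the deposited values. Points are lines, 5 hip and 5 knee, and vertical bars are joint means; the HOXB3 means are 3.19 in hip and -0.71 in knee lines and those of TBX5 0.37 and 3.44.

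Of 25 tested HOX genes, 6 were higher and 4 lower in hip lines, with 11 and 6 adjusted over the list alone. Besides those above, HOXB7 (3.17), HOXC9 (0.85) and HOXC10 (0.83) were higher in hip lines, and HOXA13 (-1.49) and HOXA11 (-0.64) in knee lines. The fry test for change in either direction gave an adjusted p of 9.35e-08, and camera for a shared direction gave 0.248. Of 35 other limb patterning regulators 5 were higher (HAND2, MEIS1, MEIS2 and IRX5 among them) and 2 lower (TBX5 and PITX1), with 8 and 4 adjusted over the list alone. Its fry adjusted p in either direction was 6.49e-08, and the camera adjusted p was 0.749. The fry test in either direction was not particular to these lists. It also passed lining markers (adjusted p = 7.54e-05), WNT signalling (0.00648), JAK-STAT components (0.0241), histones (0.0241) and inflammatory mediators (0.0487). MEIS1, a HOX cofactor, differed by 1.37 (SE 0.228, limma adjusted p = 0.0295), with hip replicate 4 at 3.66 log2 CPM and the next hip line at 4.33.

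Of the lining fibroblast markers ITGB8, an integrin chain, was higher in knee lines (-1.13, SE 0.166, limma adjusted p = 0.0233, n = 5 per joint). The lubricin gene PRG4 (-1.77, SE 0.606), CRTAC1 (-1.66, SE 0.643) and HBEGF (1.39, SE 0.361) did not pass, and 1 member was higher and 2 lower in hip lines adjusted over the list alone. The HBEGF difference and its hip minus knee response above, of opposite sign, rest on the same Med libraries and are not independent. In the other 21 lists no member passed over all genes. Values not past the threshold included COL6A1 (0.65), COL8A1 (0.52), LOXL2 (0.86) and COL6A2 (0.41) in the matrix list, and THY1 (0.38), COL1A1 (0.9981), COL3A1 (0.52) and CXCL12 (0.61) among sublining markers. They included ADAMTS5 (-0.74), PLAUR (0.42), TIMP3 (-0.73) and TIMP1 (0.38) among proteases, and WNT5B (0.68), FZD2 (0.67), SFRP4 (-1.05) and WNT2B (0.485) in WNT signalling. Adjusted over the list alone, 2 WNT genes, 2 immediate early genes, 2 histone genes and 1 inflammatory mediator were higher in hip lines, and 2 inflammatory mediators, 1 protease and 1 hypoxia gene lower. Among chondrocyte and osteoblast markers SOX9 differed by 0.59, RUNX2 by -0.36, COL11A2 by 0.24 and ALPL by -0.51, and none passed. Camera called the matrix list (adjusted p = 0.00349), histones (0.0109) and immediate early genes (0.0174) higher in hip lines, and each had an adjusted p of 0.917 with an estimated correlation. None of SOCS3, STAT3, JAK1, JAK2, TYK2, IL6R and IL6ST passed, with differences between -0.11 for JAK1 and 0.26 for SOCS3.

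The libraries of the joints also differed in measures taken over whole libraries. One was the ratio of total recovered reads to the depth behind the deposited values. It was 1.022 ± 0.00866 in hip and 0.979 ± 0.00643 in knee lines (SD, n = 5 each, exact permutation p = 0.00794, the smallest possible). The share of reads in the 10 most abundant genes was 10.28% ± 0.706 and 8.53% ± 0.508 (SD, n = 5 each, exact permutation p = 0.00794). The slope of log2 CPM on GC content, taken relative to the mean of all libraries, was 0.867 higher in hip than in knee lines (SD 0.322 in each joint, n = 5 each, exact permutation p = 0.0159). Total recovered reads (9.353 and 9.428 M, n = 5 each, exact permutation p = 0.825) did not differ beyond the spread between lines. Nor did the mitochondrially encoded share (2.945% and 3.041%, n = 5 each, exact permutation p = 0.627).

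The count of 85 moved with single lines: it was 10 without hip replicate 1, 23 without hip replicate 2, 21 without hip replicate 3, 142 without hip replicate 4, 20 without knee replicate 1, 49 without knee replicate 2, 26 without knee replicate 3, 30 without knee replicate 4 and 24 without knee replicate 5. HOXB3, HOXB4, HOXB7, HOXB-AS1, HOXD9 and TBX5 passed in each of the 10 fits without 1 line, and HOXB2 passed in all but the fit without hip replicate 1. The call was lost in 3 of the 10 fits for ITGB8, 4 for RARRES2, 5 for HOXD10, PITX1 and C14orf39, 6 for HAND2, HAND2-AS1, EYA1, MEIS1 and PCDH10, 8 for IL12A, IL12A-AS1, PSG1 and ABCB5, and 9 for AJAP1. No variance trend lost HAND2, HAND2-AS1, EYA1, MEIS1, AJAP1, PSG1 and ABCB5, voom lost HOXD10, PCDH10, AJAP1, PSG1 and ABCB5, and removal of the GC and length trend lost IL12A-AS1, AJAP1, PSG1 and ABCB5. HOXD10 and AJAP1 were lost with log2(CPM + 1), and ABCB5 with quantile normalization or robust moderation. The hip and knee ranges did not overlap for 590 genes, or 3.63% of those tested, where chance gives 0.794% for a single gene. Genes are not independent, and this count was not compared with other splits. The ranges of 83 of the 85 did not overlap either, but these were called on the same values, so this adds no evidence.

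With IL-6, as in Med, HOXB2, HOXB3 and HOXB4 were higher in hip lines and TBX5 and HOXD9 in knee lines. HOXB3 differed by 4.01 (SE 0.374, limma adjusted p = 0.00359, n = 5 lines per joint), HOXB4 by 3.51, HOXB2 by 3.29 and HOXB-AS1 by 3.06. Higher in knee lines were TBX5 (-2.67, SE 0.306, adjusted p = 0.00506), HOXD9 (-2.05), PITX1 (-1.46), IL12A (-1.31) and the prohormone convertase PCSK1 (-0.9992). The call of PCSK1 was lost in each of the 10 fits without 1 line and in most other settings. That of PITX1 was lost in 8 of these fits and with no variance trend, robust moderation or a mean of at least 3 log2 CPM. HOXB-AS1 lost its call in 3 of these fits. In all, 39 genes passed, 25 higher and 14 lower in hip lines, and 24 differed at least 2-fold. Of these, 27 also passed in Med and 12 did not, 58 passed in Med only, and all 85 genes of the Med comparison kept their sign. The r of 0.821 across genes between the comparisons comes from the same lines and is no independent evidence. The change of the difference between joints from Med to IL6 is the hip minus knee response tested above, in which 0 genes passed. HOXB4 had 126 reads in hip and 1 in knee lines, a ratio of 128 (95% counting interval 22.5 to 5080).

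Of 25 HOX genes 5 were higher (HOXB2, HOXB3, HOXB4, HOXB7 and HOXC8) and 2 lower (HOXD9 and HOXD10) in hip lines with IL-6, with 10 and 5 adjusted over the list alone. Of 35 other limb regulators 5 were higher (HAND2, MEIS2, IRX5 and PRRX2 among them) and 2 lower (TBX5 and PITX1), with 8 and 4 adjusted over the list alone. Camera called the matrix list (adjusted p = 0.00964), histones (0.00964) and HOX genes (0.037) higher in hip lines, and interferon-stimulated genes (0.0099), the TGF-beta response (0.0111) and lining markers (0.0118) lower. With an estimated correlation none of these 6 lists passed, and the smallest adjusted p was 0.307, for lining markers. The count of 39 was 16, 13, 12, 69 and 79 without hip replicates 1 to 5 in turn, and 23, 23, 24, 22 and 15 without knee replicates 1 to 5.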

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

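The tests of whole lists between lines were reworded only after the result was seen, and the removal of a GC and length trend was added after the data were examined. The other tests were set before their results were seen.

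The genes that separate hip from knee lines came with libraries that differed between the joints in GC slope, scaling and the share of their most abundant genes, so GC and length bias was weighed. For the 19 HOX and limb regulator genes, removing each library's trend left a median of 0.991 of the fold change (95% interval 0.965 to 1.03). Of these genes 16 still passed, which argues against that bias as the whole cause. The intervals here resample genes, and neighbouring HOXB genes and antisense partners among them are not independent. For the other 66 genes the median was 0.901 (0.854 to 0.953) and 24 still passed. Their median size went from 0.735 to 0.654 with a median SE of 0.123 before and after. The median adjusted p after removal was 0.066, close to the threshold. Whether calls ended for that closeness or through loss of a GC-related part was not tested. All 66 kept their sign, and the interval of 0.854 to 0.953 argues against the trend measured here as the main source of their fold changes. Scaling and the share of the most abundant genes also followed the joint and were not removed for either set of genes. For both sets a technical and a biological origin therefore cannot be told apart, and a difference by joint stays open as the biological explanation.

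With IL-6, some named genes overlap another gene on the opposite strand and moved with it, as DDIT4-AS1 did with DDIT4. If reads of overlapping genes are shared, such pairs should correlate more than neighbours do. Over 1690 overlapping pairs the IL-6 log2 fold changes had an r of 0.604 across pairs, against 0.139 over 892 opposite-strand neighbours within 10000 bases, a difference of 0.465 (95% interval 0.375 to 0.546). The sign was shared by 75.4% and 57% of pairs. This is consistent with reads shared between overlapping genes, but common regulation of overlapping genes may give the same and was not tested, so DDIT4-AS1 adds no independent evidence; the differences between joints were not tested in this way.

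With a preset correlation, camera gave a hip minus knee difference in IL-6 response below 0 for STAT3 targets (adjusted p = 0.00356), interferon-stimulated genes (0.000432), extracellular matrix genes (0.000521), the TGF-beta response (0.000823) and adipocyte markers (0.00652). With an estimated correlation these were 0.593, 0.561, 0.561, 0.561 and 0.261, and with fry 0.70, 0.70, 0.70, 0.70 and 0.551. An exact two-sided permutation of the joints over the 10 lines gave, for the mean response of the first 4 lists, a smallest p of 0.0873 (matrix genes), so the spread of whole lists between lines is a candidate explanation for them. For the 5 adipocyte markers the exact p was 0.0159, or 0.0795 adjusted over the 5 lists, with means of -0.334 ± 0.11 in hip and -0.00524 ± 0.208 in knee lines (SD, n = 5 each). This was first set as an unadjusted test and was put on the adjusted p after 0.0159 was seen, so whether this list differs by joint cannot be told apart from line-to-line spread.

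Of 211 groups of 5 lines, 10 held a line far from the other 4 by Dixon's test, where chance gives 10.6. The gap as a share of the range is given for each. The IL-6 response of APOL4 in hip lines had a gap of 0.778, with replicate 3 at 6.18 and the next at 4.18. SLC2A3 in hip lines had 0.712, with the same line at 1.66 and the next at 1.12. CDH5 in knee lines had 0.715, with replicate 5 at -1.43 and the next at -0.41. DES in hip lines had 0.774, with replicate 1 at -0.04 and the next at 0.49. In Med, HOXB4 in knee lines had a gap of 1, with 1 line at -1.68 and the others at the floor of -2.23. HOXB2 in knee lines had 0.713, with replicate 5 at 1.75 and the next at 0.00. TBX5 in hip lines had 0.813, with replicate 5 at 1.84 and the next at 0.20. IL12A-AS1 in knee lines had 0.71, with replicate 3 at 0.78 and the next at 1.14. MEIS1 in hip lines had 0.713, with replicate 4 at 3.66 and the next at 4.33. The mitochondrially encoded share in knee Med libraries had 0.769, with replicate 4 at 3.51% and the next at 3.07%.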

How the results depend on the processing

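Limma-voom, removal of the GC and length trend and the list test with no replicate block were chosen after seeing the data; all other settings were fixed before. No named gene past the threshold changed direction in the settings run; named genes that did not pass were not followed. The balance of IL-6 calls turned to more lower than higher under quantile normalization (2031 higher and 2906 lower over all lines, 1318 and 1323 in hip, 1377 and 1497 in knee lines) and, over all lines, with the GC and length trend removed (2282 and 2505). The cause of the changes below was not tested unless stated. The IL-6 counts stayed within 1.5 times of 4296, 2329 and 2656 except with no replicate block, where they were 1452, 529 and 634. Of 69 named genes past the threshold over all lines, 46 passed with no replicate block. The GC and length removal gave 4787 genes over all lines and voom 4326. Without 1 line the counts were 3751 to 4180 over all lines, 1681 to 2197 in hip lines and 1950 to 2486 in knee lines, from fewer samples. The difference between joints was 0 genes in each setting except leaving out lines, 0 to 6, where only the fit without knee replicate 2 gave 6. Hip against knee in Med, 85 genes, was 280 with line as a random effect, 199 with array weights, 39 with no variance trend and 47 with the GC and length trend removed, and 10 to 142 without 1 line. In IL6, 39 genes became 197, 93, 23 and 25 in the same order, 25 with voom, 11 at a mean of at least 3 log2 CPM, which tests fewer genes, and 12 to 79 without 1 line. For the IL-6 response 10 lists passed with camera, 3 with an estimated correlation, 15 with fry and 8 with no replicate block, where WNT signalling and hypoxia were lost. The STAT3 score difference of -0.164 lay between -0.268 and -0.0875 without 1 line and did not pass in any setting. Scaling settings moved the median of all genes by less than 0.1. The setting with no filter removed no gene and says nothing. Depth limits the genes near the floor, such as HOXB4, HOXB7 and HOXD10, where fitted folds depend on the prior.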

Other observations

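The genes named in the next 2 paragraphs were chosen after their values were seen, and the test on level and spread together was chosen only after the result was seen. The other tests here were set before their results were seen.

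IL-6 lowered many of the HOX genes that these cells express. Of 25 tested members 13 fell and 0 rose, with 15 and 0 adjusted over the list alone. HOXA13 fell by 1.07 (SE 0.093, limma adjusted p = 1.82e-09), HOXA10 by 0.41 (SE 0.0411) and HOXA11 by 0.41 (SE 0.0547), all homeobox genes of the HOXA group. With camera the adjusted p of the list was 3.81e-05, and the adjusted p was 0.0984 with an estimated correlation. Under quantile normalization 13 also fell and 0 rose. In WNT signalling 9 of 28 fell and 3 rose (FZD5, FZD7 and WNT9A), with 10 and 3 adjusted over the list alone. The WNT antagonist DKK1 fell by 1.06 (SE 0.0582, limma adjusted p = 3.81e-13), the receptor FZD2 by 0.62 (SE 0.0649) and the ligand WNT5A by 0.46 (SE 0.0424). For the WNT list the camera adjusted p was 0.00259, and the adjusted p was 0.0401 with an estimated correlation and 0.175 with no replicate block. Of 35 other limb patterning regulators 10 rose and 10 fell, with 11 and 15 adjusted over the list alone (camera adjusted p = 0.405). Among inflammatory mediators IL6 itself rose by 1.60 (SE 0.184), LIF by 1.09 (SE 0.101) and PTGS2, the inducible prostaglandin synthase, by 1.02 (SE 0.15).

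The difference in response between joints gave 0 genes with all lines and in 9 of the 10 fits without 1 line. In the fit without knee replicate 2 the difference, hip minus knee, was 0.56 for NEAT1 (SE 0.0777, limma adjusted p = 0.00501), 0.58 for MALAT1 (SE 0.0867, adjusted p = 0.00606), 0.42 for MEG3 (SE 0.078, adjusted p = 0.0496) and 0.95 for GOLGA8B (SE 0.143, adjusted p = 0.00606). It was -0.83 for JUNB (SE 0.133, adjusted p = 0.0106) and -0.39 for B4GALT1 (SE 0.071, adjusted p = 0.0496). Other splits were run with all 10 lines only, where 82 of 99 gave 0 genes and the highest gave 40. None were run without knee replicate 2, so these 6 calls cannot be weighed against chance. On their own they establish no difference by joint.

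A hypothesis was that genes which separate the joints respond to IL-6 more often than other genes. Of the 85 genes called between joints in Med, 32, or 37.6%, were also called for IL-6, against a mean of 25.8% (95% of draws 16.5% to 35.3%) in 10000 draws matched on expression level. The observed share was above 99.2% of draws, which is consistent with the hypothesis. When draws were matched on level and on the spread within lines, their mean was 28.4% (20% to 37.6%) and 96.5% lay below the observed share, so the possibility that genes with little spread are easier to call in both tests stays open. Among the 32, genes higher in hip lines went up with IL-6 in 4 cases and down in 13, and genes higher in knee lines went up in 6 and down in 9.

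A second hypothesis was that the level of a receptor or kinase gene before IL-6 may set the size of a line's STAT3 target response. Over 10 lines and 4 genes the largest r was 0.653, for IL6R (permutation p = 0.0458, adjusted p = 0.144; Spearman rho 0.685, permutation p = 0.0344, adjusted p = 0.109). Without the 2 lines farthest from the median IL6R level r was 0.41, so the relation was weaker without them. Leaving out the most extreme levels also narrows the range, which can lower r by itself. IL6ST had an r of -0.596 (permutation p = 0.0719, adjusted p = 0.144) and a rho of -0.636 (permutation p = 0.0545, adjusted p = 0.109), with an r of -0.31 without the 2 farthest lines. JAK1 had an r of 0.176 (permutation p = 0.623, adjusted p = 0.623) and a rho of 0.115 (permutation p = 0.76, adjusted p = 0.76), and JAK2 an r of -0.358 (permutation p = 0.328, adjusted p = 0.437) and a rho of -0.176 (permutation p = 0.631, adjusted p = 0.76). Without the 2 farthest lines r was 0.348 for JAK1 and 0.323 for JAK2. None passed after adjustment, and the test was not repeated within each joint.

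Other splits of the same samples show how often relabelling gives as many calls. For the IL-6 response over all lines, labels were exchanged within some lines, so that each line kept a library of each label. In 100 of the 512 assignments only the real 1 gave 4296 genes, and the highest other gave 0. This is a share of 1 in 100, under 0.05. For hip lines (2329) and knee lines (2656) 1 of 16 assignments gave as many and the highest other gave 0, but 16 are too few for a share under 0.05. For hip against knee, 100 of the 126 splits of 10 lines into 5 and 5 were drawn. In Med 1 split, the real one, gave 85 genes and the highest other 30. In IL6 1 split, again the real one, gave 39 and the highest other 20. Each share was 1 of 100, under 0.05, and both comparisons used the same 10 lines. Without 1 line the counts were 10 to 142 in Med and 12 to 79 in IL6, so chance is unlikely but not excluded. For the difference in response the real count was 0, so all 100 splits gave at least as many and the comparison says nothing about chance. The highest other split gave 40, and a structure among the lines, which may give such a count, was not tested.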
